A study of Mus musculus with 12 samples.

How the data were processed

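RNA was measured in 12 libraries of alveolar macrophages, the macrophages that live in the air spaces of the lung, sorted by flow cytometry from enzymatically digested lungs of C57BL/6 mice. Per the labels, each library came from 3 pooled mice aged 6 weeks. Infected mice had received the encapsulated yeast Cryptococcus neoformans through the trachea 9 hours before collection. The libraries were made with an ultra-low-input SMARTer amplification and a Kapa library kit and sequenced as paired 50 bp reads, per the labels' protocols. The labels name no molecular identifiers, so amplified copies of one molecule can be counted more than once, and depth alone understates the error. The treatment text is the same for all 12 libraries, and the naive groups were taken from the titles.

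The authors deposited a single table of raw counts, whole numbers per feature with 1 column per library. Per the submitters' processing notes, the tools named were Trim Galore 0.4.0, STAR 2.4.1d, HTSeq 0.6.1p1 and edgeR 3.8.5, without their roles or settings. The genome build, the annotation and the strand setting are not given in the sources used here. All 63677 rows carry identifiers with the prefix ENSG, which Ensembl uses for human genes, while the labels give mouse as the organism. None of the rows matched the 55450 mouse gene identifiers of the reference annotation (0 matches). The count table does not pair its identifiers with gene symbols, so features are given here by identifier, at most 2 that rose and 2 that fell, and with no gene name or position. Whether reads of mouse RNA were assigned to a genome of another species was not settled here. If they were, a feature's count also reflects how well its sequence matches between the species, and reads of related genes may be merged.

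The rows tested held 99.9% of all counts. Library totals ran from 14851538 to 20525936 counts, and 38091 rows had no count in any library. No row lacked a feature identifier. Each column was matched to its sample through the code in that sample's description, and all 12 columns were used. Groups were taken from the sample titles, which split infected macrophages into CXCL2+ and CXCL2− (CXCL2 is a chemokine that attracts neutrophils) and FM+ and FM−, and naive macrophages into FM+ and FM−. The labels do not say what FM stands for or how CXCL2 was detected. Each of the 6 groups had 2 libraries. The labels name pools of mice for each repeat, but do not say whether the libraries of one repeat were sorted from the same pool, or that the repeats were separate experiments. The p-values measure the spread between these libraries.

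Differential abundance was tested with edgeR 4.0.16 (R 4.3.3): trimmed-mean scaling, the default expression filter by group, and a robust quasi-likelihood fit with 1 coefficient per group over all 12 libraries, which therefore share one estimate of the spread. This left 17022 features. A feature was called at an adjusted p (Benjamini-Hochberg) under 0.05. Fold changes are log2 values from this fit, and a standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM, counts relative to the scaled library total, computed here. Principal components and correlations used log2 CPM with a prior count of 2. The comparisons were CXCL2+ against CXCL2− (mean over FM, and within FM+ and FM−), each infected CXCL2 subset against naive, FM+ against FM− (infected and naive), and the differences of these differences.

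The tests, the comparisons, the naming rule and the alternatives were fixed before the data were examined, except where stated. Features were named by rule: the largest rises and falls between CXCL2+ and CXCL2− among called features with at least 16 CPM on the higher side and the same direction in FM+ and FM−. The rule had allowed 10 per direction, had covered 5 comparisons and had required a gene symbol. With no symbols, it was reduced after the table had been seen to 2 per direction from this comparison, and these 4 features are followed throughout. The rule's remaining parts, a fixed set of always-reported genes (among them Cxcl2 itself, as a check of the sort) and the 34 gene lists (20 of pathways and 14 of markers of other cells), could not be applied. No content of another cell type was therefore measured, and the sort was not checked on its marker.

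Alternatives were median-ratio scaling (RLE), DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a stricter filter of 5 CPM in 2 libraries, fits of only the groups compared, a replicate block, the same block nested in infection status, a block for the library number, sums of same-numbered libraries over FM, and leaving out each library. The library number is the trailing number of the description code: infected replicate 1 has numbers 21 to 24, infected replicate 2 has 31 to 34 and the naive libraries have 35 to 38. Chosen after seeing the data were fits within each number range, thinning to the smallest total, library totals with no scaling factor and leaving out the 10 most counted features.

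Whether replicate numbers pair the libraries was judged from correlations and not from counts of calls. Differences between replicate 1 and replicate 2 correlated across features for all 6 pairs of infected groups (Pearson r from 0.29 to 0.66), and at 0.25 between the naive groups. Between infected and naive groups r ran from −0.21 to 0.14. Among infected libraries the numbers were therefore taken as pairs, and blocked results are given beside the unblocked ones. For infected against naive cells these correlations give no ground for pairing, so the replicate block is a weak alternative there. The library-number block has all naive libraries in the range of infected replicate 2. It thus sets naive cells against the fitted level of that single infected repeat. The steps were tested on simulated counts with 200 changed features among 17022. For CXCL2+ against CXCL2− over both FM gates, 32% of features changed 2-fold and 84% of those changed 4-fold were recovered, and 7.2% of the calls were false. Within FM+ the shares recovered were 6% and 57%, and 8.7% of the calls were false. These simulations drew each library independently, without the variation shared by same-numbered infected libraries, and with the same spread in infected and naive libraries. The changed features were taken only from those above a minimum total count. Recovery and false shares in the real libraries may therefore be worse.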

Results

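The series profiled alveolar macrophage subsets from lungs infected with Cryptococcus neoformans for 9 hours, with macrophages of naive mice for comparison. There were 8 infected libraries, 2 each of FM+ CXCL2+, FM+ CXCL2−, FM− CXCL2+ and FM− CXCL2− cells, and 4 naive libraries, 2 each of FM+ and FM− cells. Library totals were 16693053 to 20525936 counts in the infected libraries and 14851538 to 16995434 in the naive ones. Between 19455 and 20344 features had at least 1 count per library. The most counted feature of a library took 1.08% to 1.72% of its counts. Features are named by identifier, since the count table does not pair identifiers with symbols, and they carry the prefix ENSG although the animals were mice.

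A check for a library deposited more than once found none among all 66 pairs of libraries, whose lowest chi-square statistic per degree of freedom was 3.94. Between the 2 replicates of a group it ran from 11.1 in naive FM− to 93.1 in infected FM+ CXCL2+ cells. It says nothing else of the replicates, because separate pools of mice and amplified reads exceed counting noise in any case. The first principal component held 34.4% of the variance. It placed the 4 infected replicate 1 libraries between −75.1 and −20.3, and all other libraries between 14.4 and 45.7. The second component held 22.9%. It placed the CXCL2+ libraries between −71.8 and −11.7, the CXCL2− libraries between −0.004 and 23.8, and the naive libraries between 21.9 and 39.4. Infected replicate 1 also differs from the remaining libraries in its library numbers. Among infected libraries 3276 of 16850 features were called between replicate 1 and replicate 2 in edgeR's quasi-likelihood test with a term for each group.

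**Figure D1:**
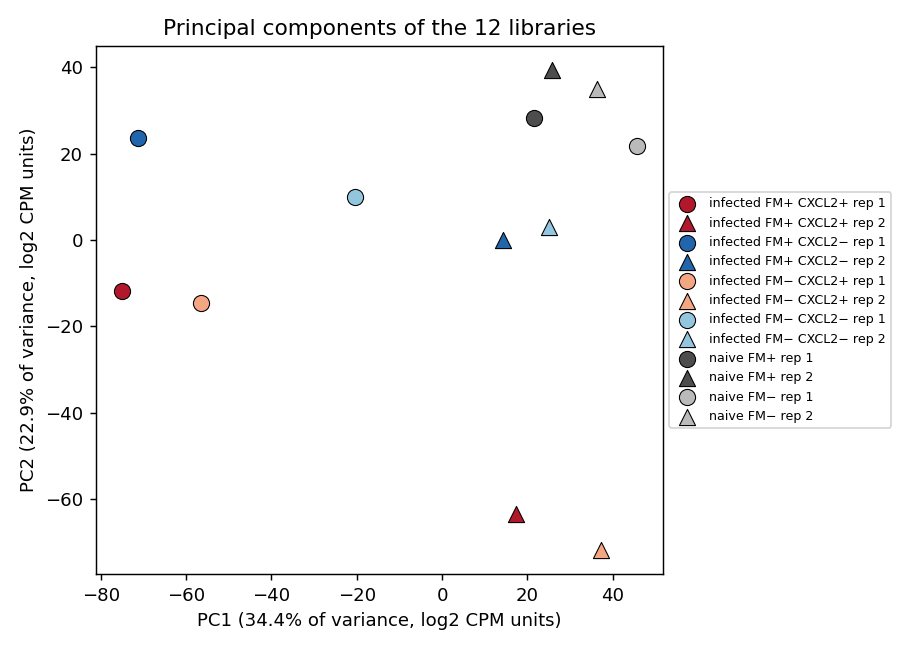
Principal components of log2 CPM over 17022 features, PC1 (34.4% of variance) on the x axis and PC2 (22.9%) on the y axis, 1 point per library, colour for the group and shape for the replicate. Infected replicate 1 libraries lie at PC1 values of −20.3 or below, and CXCL2+ libraries lie lowest on PC2 among libraries of the same replicate.

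The first comparison asked which transcripts distinguish CXCL2+ from CXCL2− macrophages sorted from infected lungs. Over both FM gates, 308 of 17022 features were called, 152 higher and 156 lower in CXCL2+ cells, with a median change among them of 0.99 on the log2 scale. At least a 2-fold change was seen in 147 of them. The fit shares its spread with the naive libraries, which are not part of this comparison. Naive replicates differed less, by a root-mean-square of 0.49 to 0.52 on the log2 scale against 0.75 to 0.98 in infected groups. The p-values of this comparison may therefore be too small, and with the infected libraries alone edgeR called 7 features. Neither fit had a term for the replicate. Variation shared by same-numbered infected libraries then stays in the spread, which can make p-values too large. The counts with a replicate block, which were larger, are given below. The largest rise under the naming rule was in ENSG00000122641, at 712 CPM ± 89.0 (SD, n = 4 libraries) in CXCL2+ and 87.9 CPM ± 24.8 (SD, n = 4) in CXCL2− cells. Its log2 fold change was 3.06 with an SE of 0.20 and an adjusted p of 0.00107. ENSG00000151012 rose from 20.3 CPM ± 10.6 to 124 CPM ± 51.3 (SD, n = 4 each), a log2 fold change of 2.65 with an SE of 0.53 (adjusted p 0.0443).

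On the side of CXCL2− cells, ENSG00000173369 stood at 184 CPM ± 185 (SD, n = 4) against 15.6 CPM ± 10.1 (SD, n = 4) in CXCL2+ cells, and its log2 fold change was −3.29 with an SE of 0.57 (adjusted p 0.0279). Its CXCL2− level was 311 CPM ± 196 (SD, n = 2) in FM+ and 57.2 CPM ± 12.2 (SD, n = 2) in FM− cells. ENSG00000178573 was at 16.1 CPM ± 11.7 in CXCL2− and 1.68 CPM ± 0.723 in CXCL2+ cells (SD, n = 4 each), a log2 fold change of −3.10 with an SE of 0.55 (adjusted p 0.0286). For all 4 features both FM gates showed the direction in both replicates. This is no separate support, since the naming rule required the same direction in FM+ and FM− and chose the features from these libraries. The call of ENSG00000122641 was lost in 1 of 26 alternatives, library numbers 21 to 24 alone. The other calls were less secure, although no alternative turned their direction. In edgeR with the replicate block they held, at adjusted p 0.000212 for ENSG00000151012, 0.00134 for ENSG00000173369 and 0.0308 for ENSG00000178573. With the block nested in infection status, edgeR's adjusted p was 8.32e-05, 0.000741 and 0.00999 in the same order. ENSG00000151012 lost its call in 14 of 26 (edgeR, DESeq2 or limma-voom adjusted p from 5.14e-06 to 0.352), among them every omission of 1 library except FM− CXCL2+ replicate 1. ENSG00000178573 lost it in 15 (adjusted p from 2.02e-07 to 0.504), among them every omission except FM− CXCL2− replicate 1. Its log2 value ran from −3.97 in numbers 31 to 38 to −2.37 without FM− CXCL2− replicate 2. ENSG00000173369 lost it in 12 (adjusted p from 1.3e-08 to 0.445), among them all omissions except FM+ CXCL2− replicate 2, FM− CXCL2+ replicate 1 and either naive FM+ library. Its log2 value ran from −3.90, without FM− CXCL2+ replicate 1, to −2.86.

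**Figure D2:**
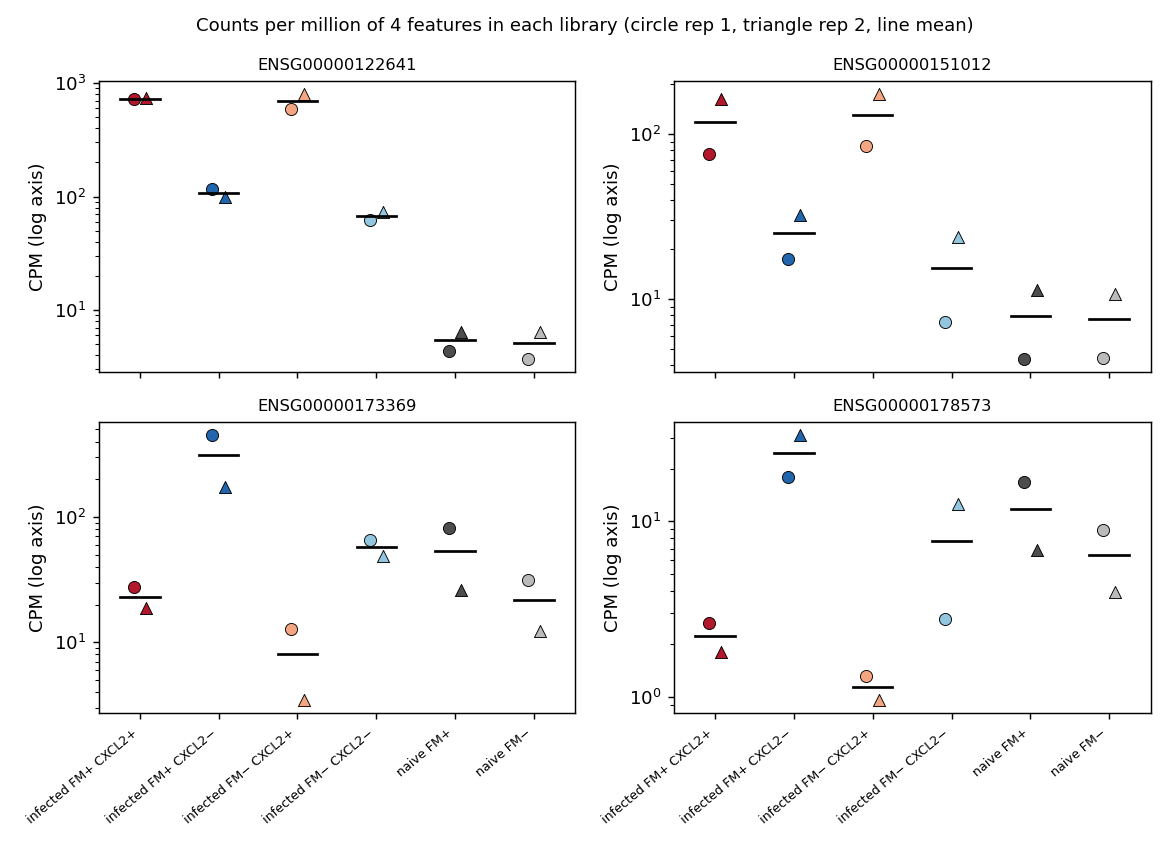
CPM (log axis) of ENSG00000122641, ENSG00000151012, ENSG00000173369 and ENSG00000178573 in the 12 libraries by group; circles are replicate 1, triangles replicate 2 and lines the mean of the 2. ENSG00000122641 has group means of 732 and 692 CPM in CXCL2+ cells, 108 and 67.6 CPM in CXCL2− cells and about 5 CPM in naive cells (5.41 and 5.08).

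With the replicate number as a block, 660 features were called (297 higher, 363 lower), all 308 among them, and 1566 with the block nested in infection status. Within library numbers 31 to 34 alone (2 libraries against 2) 3206 features were called, and within 21 to 24 alone 0 features were called, with 1646 at an unadjusted p under 0.05. In each range the 2 libraries of an arm are the FM+ and FM− gates of a single repeat. These counts therefore carry no spread between repeats. The 308 called features had the direction of the pooled estimate in both ranges wherever tested (308 of 308 in the lower range and 305 of 305 in the upper one), although both ranges had entered that estimate. The number of calls therefore depended on the fit: 901 with DESeq2, 7 in edgeR with the infected libraries alone, and fewer without most single libraries. Leaving out 1 library left 42 to 119 calls in 10 of 12 cases, all but FM+ CXCL2+ replicate 1 (225 calls) and FM− CXCL2+ replicate 1 (408).

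Whether the CXCL2 difference itself depended on the FM gate was tested as an interaction. No feature was called (0 of 17022) in edgeR's quasi-likelihood test, with 220 at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 0. The median SE over all features was 0.49 for the interaction, against 0.24 for the mean over FM. The 0 calls therefore do not show that the CXCL2 difference was alike in both gates. Within FM+ cells alone 7 features were called (4 higher, 3 lower in CXCL2+), and within FM− cells alone 7 (6 higher, 1 lower). ENSG00000122641 was among both, with log2 fold changes of 2.76 (SE 0.28, adjusted p 0.0201) in FM+ and 3.36 (SE 0.29, adjusted p 0.015) in FM− cells. With the replicate block the counts were 68 and 62, and with DESeq2 277 and 251. Leaving out 1 library gave 0 to 29 calls in FM+, where each of the 12 libraries changed the count by more than 1.5 times, and 0 to 33 in FM−, where omitting an infected FM+ library left 5 or 6 and omitting any other library changed the count by more than 1.5 times. ENSG00000122641 lost its FM+ call in 9 of 24 alternatives and its FM− call in 4 of 24. Across all features, the FM+ and FM− log2 differences had a Pearson r of 0.48, and features are not independent replicates. The FM+ and FM− differences share no library, but both hold the same replicate numbers. Between replicate 1 and replicate 2, which share neither, the r of the CXCL2 difference was 0.21.

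**Figure D3:**
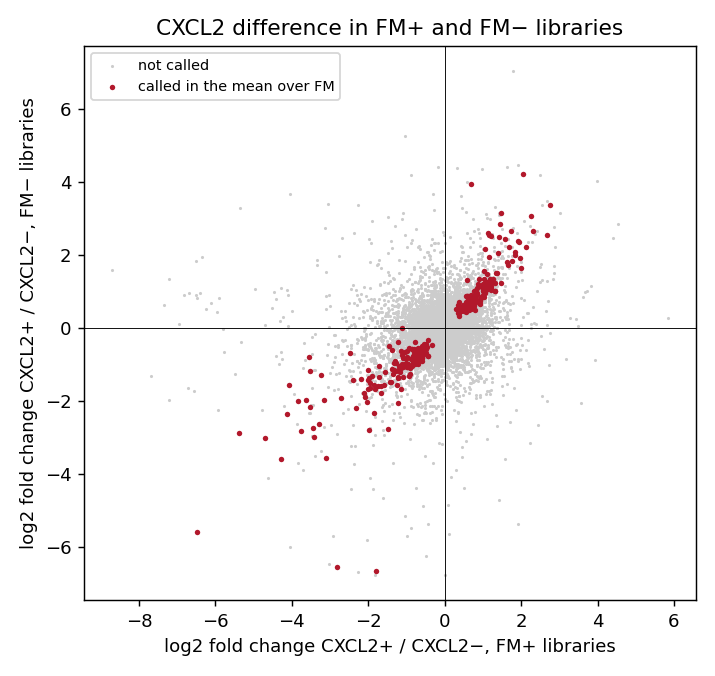
Log2 fold change of CXCL2+ over CXCL2− in FM+ (x axis) and FM− (y axis) libraries for 17022 features, 1 point each. The 308 features called in the mean over FM are red, and all of them have the same sign of mean log2 CPM difference in both gates. They were called on the mean of the 2 plotted differences, so the choice favours a shared sign. Over all 17022 features 69.9% had the same sign.

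Each infected subset was then set against naive macrophages. CXCL2+ cells differed from naive cells at 2437 features, 1272 higher and 1165 lower, with 896 changed at least 2-fold. CXCL2− cells differed from naive cells at 11 features, all 11 of them higher, with 2218 at an unadjusted p under 0.05. Larger call sets held both directions, with 271 higher and 150 lower in DESeq2, and 93 higher and 61 lower in edgeR with the replicate block. ENSG00000122641 rose in both, from 5.25 CPM ± 1.42 (SD, n = 4) in naive cells, by 7.08 on the log2 scale in CXCL2+ (SE 0.24, adjusted p 4.89e-06) and by 4.02 in CXCL2− cells (SE 0.21, adjusted p 0.000239). ENSG00000151012 rose 16.1-fold in CXCL2+ cells (SE 0.57 on the log2 scale, adjusted p 0.00268), and its value in CXCL2− cells, 1.35 (SE 0.52), had an adjusted p of 0.342. The replicate block called that value (edgeR, 1.36, SE 0.14, adjusted p 0.00931), as did the library-number block (1.80, adjusted p 0.039). Over 25 alternatives its adjusted p ran from 0.00931 to 0.85. These blocks are weak support, since replicate differences of infected and naive groups correlated at only −0.21 to 0.14. Sums of same-numbered libraries, described below, did not call the value in CXCL2− cells. ENSG00000178573 fell by 2.44 on the log2 scale in CXCL2+ cells (SE 0.54, adjusted p 0.0173), with 9.12 CPM ± 5.47 (SD, n = 4) in naive cells, a call lost in 7 of 25 alternatives. ENSG00000173369 was called in neither in edgeR without a block, with log2 values of −1.33 (SE 0.54, adjusted p 0.136) in CXCL2+ and 1.96 (SE 0.54, adjusted p 0.227) in CXCL2− cells. With the replicate block edgeR called both, −1.27 (adjusted p 0.00853) and 2.07 (adjusted p 0.0167), and so did DESeq2 (adjusted p 0.0418 and 0.00736). The library-number block in edgeR called the CXCL2+ value, −1.93 (adjusted p 0.0264), but not the CXCL2− value, 1.39 (adjusted p 0.155). The limit of the blocks given above applies here too, and sums of same-numbered libraries called neither value. The adjusted p ran from 0.00853 to 0.393 and from 0.00736 to 0.85 over the alternatives.

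Of the 152 features higher in CXCL2+ than in CXCL2− cells, all 152 were also called higher in CXCL2+ than in naive cells, and 8 were called higher in CXCL2− than in naive cells. The mean of the CXCL2− libraries lay between those of naive and CXCL2+ libraries for 147 of them, and the median CXCL2− change from naive was 0.43 on the log2 scale against 1.35 for CXCL2+. Of the 156 features lower in CXCL2+ cells, 144 were also called lower than in naive cells. The CXCL2− mean was intermediate for 127 of these 156, with a median change from naive of −0.34 against −1.33 for CXCL2+. Both steps used the same CXCL2+ libraries. In 20 simulations with no effect, 88.5% of as many features chosen as highest in CXCL2+ cells, and 92.3% of those chosen as lowest, also had that direction against naive, so the shared direction alone is favoured by the choice. With an unadjusted p under 0.05 as well, the simulated shares were 24.6% and 38.2%, against 100% and 97.4% observed. An intermediate CXCL2− value, judged by fitted fold changes, had simulated shares of 6.78% and 12.4%, against 97.37% and 81.41% observed. The simulations drew each library independently and left out that same-numbered infected libraries varied together, so these shares may be too low. Of the 11 features called in CXCL2− cells, 10 were called higher in CXCL2+ cells as well, where independent lists of these sizes would share 0.822, a number that leaves out the shared naive libraries.

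Both comparisons used the same naive libraries, so a correlation between them exceeds 0 with no effect. The observed r across features was 0.72 with a covariance of 0.305, and the 20 simulations, again with independent libraries, gave 0.51 and 0.102. With the naive replicates split between the comparisons, r was 0.51 and the covariance 0.275, and edgeR called 1 and 0 features. The split leaves same-numbered infected libraries in common, which varied together, so its covariance is no measure of a shared response. With no library and no infected replicate number in common, r across features was 0.14 to 0.32 and the covariance 0.0789 to 0.133. The difference between the infected subsets is itself the CXCL2+ against CXCL2− comparison, with its 308 calls.

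The infected and naive arms hold 2 repeats each, and same-numbered infected libraries varied together. With same-numbered libraries summed over FM, 2 sums against 2, edgeR called 157 features for CXCL2+ against naive, all among the 2437, and 0 for CXCL2− against naive, with 943 at an unadjusted p under 0.05. In these sums ENSG00000122641 kept its call in CXCL2+ cells and lost it in CXCL2− cells (edgeR adjusted p 0.116), and ENSG00000151012 and ENSG00000178573 lost theirs in CXCL2+ cells (0.0669 and 0.112). With only library numbers 31 to 38 the counts were 5759 and 1417. Each infected arm there was the FM+ and FM− libraries of a single repeat, so these counts carry no spread between infected repeats. With the replicate block the counts of all 12 libraries were 4032 and 154. Leaving out naive FM+ replicate 1 or 2 left 1386 and 1068 CXCL2+ calls, and leaving out naive FM− replicate 1 or 2 left 1252 and 1022. The CXCL2− count was 1 to 17 without single libraries, and only the library FM− CXCL2+ replicate 2 left it at 11.

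FM+ and FM− cells were compared last. In infected cells no feature was called (0 of 17022) in edgeR's quasi-likelihood test, with 710 at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 95, of which 88 were higher in FM+. The replicate block gave 1 call, and the block nested in infection status 62, of which 56 were higher in FM+. Within library numbers 21 to 24 and within 31 to 34 edgeR made 0 calls each, with 1018 and 132 at an unadjusted p under 0.05. Each of these fits again held a single repeat. In naive cells no feature was called (0), with 122 at an unadjusted p under 0.05. DESeq2 called 1 there, limma-voom 0, and edgeR on the 4 naive libraries alone called 33, all 33 higher in FM+. The main fit gives naive cells a spread shared with infected libraries, which varied more. Its 0 calls therefore do not show that naive FM+ and FM− cells are alike. The test of whether the FM difference changed with infection called 0 features, with 86 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. ENSG00000173369 had log2 values for FM+ over FM− of 1.98 (SE 0.54, adjusted p 0.743) in infected and 1.31 (SE 0.75, adjusted p 1) in naive cells. The median SE over all features was 0.24 for the infected and 0.35 for the naive FM comparison, and 0.42 for the test of their difference. The 0 calls of that test therefore do not show that the FM difference was alike with and without infection.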

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

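The fits within library-number ranges, thinned counts, unscaled totals and fits without the 10 most counted features were chosen after the results had been seen. The cause of a moved count was not tested except where named. Fits within a number range hold a single repeat of infected cells, so their counts carry no spread between infected repeats. For CXCL2+ against CXCL2− over both gates (308 calls), counts were 901 with DESeq2, 508 with no filter, 7 with only the groups compared, 660 with the replicate block, 1566 with the nested replicate block, 1616 with the library-number block, 0 in numbers 21 to 24 and 3206 in 31 to 34; leaving out 1 library gave 42 to 408. Within FM+ (7 calls) they were 277 with DESeq2, 111 with no filter, 21 with the stricter filter, 0 with only the groups compared, 68 with the replicate block, 378 with the nested one, 461 with the library-number block and 17 with unscaled totals, and 0 to 29 without 1 library. Within FM− (7 calls) they were 251 with DESeq2, 117 with no filter, 0 with only the groups compared, 62 with the replicate block, 360 with the nested one and 407 with the library-number block, and 0 to 33 without 1 library. The interaction of CXCL2 and FM had 2 calls with DESeq2 and 0 in every other setting, those without 1 library included. CXCL2+ against naive (2437 calls) moved to 4032 with the replicate block, 4151 with the library-number block, 157 with summed libraries and 5759 in numbers 31 to 38, and ranged from 1022 to 2290 without 1 library; DESeq2, limma-voom, RLE and both filters stayed within 1.5 times. CXCL2− against naive (11 calls) moved to 421 with DESeq2, 2 with limma-voom, 152 with no filter, 17 with the stricter filter, 30 with only the groups compared, 154 with the replicate block, 601 with the library-number block, 0 with summed libraries, 25 with unscaled totals and 1417 in numbers 31 to 38, and ranged from 1 to 17 without 1 library. FM+ against FM− in infected cells (0 calls) gave 95 with DESeq2, 20 with no filter, 1 with the replicate block, 62 with the nested block and 90 with the library-number block, and 0 without any 1 library. In naive cells (0 calls) it gave 1 with DESeq2, 3 with the library-number block, 33 with only the groups compared, 0 with the replicate block and 0 without any 1 library. The interaction of FM and infection stayed at 0 in all settings run; a fit of only the groups compared gives it no separate value, since it uses all 12 libraries. The 10 calls shared by both infected subsets against naive became 0 when the naive replicates were split, where fewer libraries entered each fit. RLE scaling and thinning left all counts within 1.5 times, and neither RLE nor unscaled totals moved the median of all features by more than 0.1 on the log2 scale. Of 496 values of the 4 named features, 407 stayed on their side of the threshold, 64 lost and 24 gained the call, and 1 changed sign: ENSG00000178573 in CXCL2− against naive, an uncalled value, was −0.074 without FM− CXCL2− replicate 2. Without other single libraries it reached 1.04 at most, and over all alternatives 1.26. ENSG00000122641 kept its call between CXCL2+ and CXCL2− in 25 of 26 alternatives, against 12, 14 and 11 of 26 for ENSG00000151012, ENSG00000173369 and ENSG00000178573. The planned gene list tests were not run, since the identifiers were not matched to symbols.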

Other observations

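The main comparisons and the DESeq2 and block counts repeated here had been planned. The other tests in this part were chosen after the results they bear on had been seen. For FM+ against FM− edgeR called 0 features in infected and 0 in naive cells (710 and 122 at an unadjusted p under 0.05; DESeq2 called 95 and 1), yet the differences correlated between separate libraries. Across 17022 features the FM log2 difference of infected cells correlated with that of naive cells at a Pearson r of 0.45 (Spearman rho 0.23), where neither group enters the other's value. Exchanging the FM labels within the 6 pairs of same-numbered libraries in all 64 ways gave an r as high in 2 cases (exact permutation, one-sided p = 0.03125, the smallest possible; highest other r 0.37), but this takes the CXCL2 gates of one repeat as independent, and with repeats as units 2 of 16 assignments did (exact p = 0.125, again the smallest possible), which cannot pass 0.05. Without the 170 features (1%) that differed most, r was 0.25 against at most 0.23 in the other assignments, and the p-value, again the smallest possible, was 0.03125 (exact permutation), so whether a few extreme features are the source stays open. A candidate explanation, left open by these tests, is a small difference between FM+ and FM− cells that is present with and without infection; a difference in which other cells enter each gate would look the same and was not tested, since no marker could be read.

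Infected replicates 1 and 2 differed at 3276 features in a fit with a term for each group. Thinning all libraries to the smallest total left 3215, which argues against a difference in depth as the whole cause, and the 10 most counted features can shift all others by at most 0.041 on the log2 scale, which argues against a few dominant features. The naive replicates, all within library numbers 35 to 38, differed by a root-mean-square of at most 0.52 on the log2 scale, and the infected groups by 0.75 to 0.98. This is consistent with a batch of library preparation or sequencing, and as much with infected mice of each repeat that responded differently. Library number range and repeat are the same split among infected libraries, so batch and mice cannot be told apart.

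CXCL2+ cells had 2437 calls against naive and CXCL2− cells 11, but the size of the gap depended on the fit, with 3385 and 421 calls in DESeq2, 4032 and 154 with the replicate block, 4151 and 601 with the library-number block, and 5077 and 2218 at an unadjusted p under 0.05. The main fit has one spread for all groups, and the median SE was 0.24 in both comparisons. These counts therefore cannot test a larger spread between CXCL2− replicates as the cause. Its premise was not met, since the root-mean-square replicate difference of CXCL2− cells was lower than that of CXCL2+ cells (difference −0.17, from means of 0.79 and 0.97). In thinned libraries the ratio was 159. Totals were already close, at 16920155 to 20525936 in CXCL2+ and 16693053 to 19315816 in CXCL2− libraries. Thinning therefore had little difference in depth to remove and is no strong test of it. Within library numbers 31 to 38 the ratio was 4.06, so in these libraries the number range is not the whole source of the gap. The size of the ratio depends on the range. Each infected arm there was the FM+ and FM− libraries of a single repeat, so the ratio carries no spread between infected repeats. A response to infection that is weaker in CXCL2− cells, or a CXCL2− gate that mixes responding and resting cells, stays open as an untested hypothesis, as does a different share of other cells in the gate.

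The 8 libraries of each comparison of 4 against 4 were also split in all 35 ways, with 2 groups and no further term. For CXCL2+ against naive the real split called 3690 features, 1 of 35 splits reached that and the highest of the others called 0. For CXCL2− against naive it called 214, 1 of 35 reached that and the highest other was 8. These splits exclude chance only if single libraries are exchangeable; same-numbered infected libraries varied together, and with the 2 repeats of each arm as units the splits are too few for a share under 0.05. For CXCL2+ against CXCL2− it called 164 and 2 of 35 splits reached that, a share above 0.05, so a chance split is not excluded by this count. The other split was replicate 1 against replicate 2, with 2679 calls, which points to the structure described above. Among the 8 splits that part all 4 same-numbered pairs, as the real one does, the other 7 called 0 features each. With only 8 such splits no outcome could reach a share under 0.05, so they do not exclude a chance split either. For FM+ against FM− in infected cells the real split called 0, so all 35 reached it and the highest other was again the replicate split with 2679.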
